A study of Sus scrofa domesticus with 8 samples.

How the data were processed

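Gene expression of porcine ovarian granulosa cells was measured on 8 Affymetrix whole-transcript arrays, with 2 arrays at each of 4 times, 0 h, 48 h, 96 h and 144 h of culture. Total RNA was labelled with biotin and fragmented, per the labels' protocols. The deposited table held log2 intensities that the authors had made by robust multi-array averaging (RMA), per the submitters' processing notes. RMA corrects the background, normalizes the arrays to each other and summarises the probes of a feature. Its software, version and settings are not given in the sources used here. Because RMA sets the arrays to a common distribution, a change shared by most transcripts would not appear in these values. The table held 27558 features with no missing value, and it was used without a further normalization or filter. Each of its columns names its own sample.

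Groups were taken from the time point in the labels and replicate numbers from the sample titles. No label gave an array batch, so a batch that followed time cannot be told apart from time. The number of arrays, 2 per time, limits the precision. Genes were named through GEO's platform annotation, which can be old, and 6 symbols were updated through the gene identifier. Of the features, 11735 had 1 gene symbol, 612 had several and 15211 had none in the table used. Of the 612, 239 repeat a single symbol and 373 hold different ones. Features with several or none were tested but not named. The named features stood for 10707 genes. Where a gene had more than 1 feature, which held for 1962 features, the feature with the highest mean over all arrays was used.

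A linear model with 1 mean per time was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which left 4 residual degrees of freedom and a prior of 3.98. The model pools the spread of all times for a feature, although the SD of the difference between the 2 arrays of a time ran from 0.162 at 96 h to 0.382 at 144 h. All 6 pairs of times were compared by limma's moderated test, two-sided, and the 4 times together by its F test. P-values were adjusted by the Benjamini-Hochberg method over all 27558 features within a comparison, and a feature was called at an adjusted p below 0.05. The median standard error of a difference was 0.143 on the log2 scale. Gene lists were fixed before the data were examined: 31 lists with 607 places, of which 386 had a feature. Each list was tested with camera, from limma, with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the 31 lists within a comparison. The members of each list were also adjusted over the list alone.

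The genes named in the text follow a rule fixed before the data were examined. It takes the 10 called genes with the largest rise and the 10 with the largest fall at each time against 0 h, and 5 each way between later times, where both arrays of one time lie above or below both of the other. It adds up to 4 measured members per list with the largest change at 144 h, and a set of granulosa, matrix and cell cycle genes. Of that set FSHR, CYP19A1, STAR, CYP11A1, INHA, FOXL2, VIM, MKI67, PCNA and CCNB1 had no named feature and were not analysed here. A gene outside the rule is said to be chosen after its value was seen.

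The steps were tested on 8 simulated arrays over 27558 features, made from each feature's mean and model spread over all 8 real arrays. In each of 10 runs, 200 features were changed on the 48 h arrays and tested against 0 h. The model recovered 6.27% of changes of 0.5 on the log2 scale, 85.2% of 2-fold changes and 99.7% of 4-fold changes, and 5.29% of its calls were false. In the real comparison of 48 h with 0 h, 8260 features were called, many more than the 200 changed here. The Benjamini-Hochberg cut-off depends on the share of changed features, so these recoveries do not measure the recovery in the real comparisons. Camera found the moved list, and 8 of 200 unmoved lists had an unadjusted p below 0.05. The simulated genes varied independently, whereas the estimated correlation was 0.324 for fibrillar matrix and 0.771 for immediate early genes. The 8 of 200 therefore does not measure false list calls among correlated genes. Calls against 0 h share the 0 h arrays. The overlap, covariance and correlation were therefore also computed in 20 simulations in which all 8 arrays, 0 h included, were simulated without change.

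Alternatives fixed before the data were examined were median centring, quantile normalization and cyclic loess of the 8 arrays, and leaving out dim features. That filter kept the 18019 features above their array's 40th percentile on at least 2 arrays. The others were eBayes with trend and robust, a fit to only the 4 arrays compared, the replicate number as a block, 1 feature per named gene, an adjusted p below 0.01, a fold of at least 2, an estimated correlation in camera, and leaving out each array in turn. A fit without the 96 h arrays was chosen after seeing the data. So was a wider naming, in which features that repeat a single symbol were named too and SHAS2 was counted as HAS2 through the synonyms of the reference. It gave 10904 named genes and added 12 places to 9 lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.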

Results

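Gene expression was measured in porcine ovarian granulosa cells, the somatic cells that line the ovarian follicle and surround the oocyte, before culture and during 144 h of culture. The study used 43 crossbred Landrace gilts, and the cells were kept in DMEM with 2% fetal bovine serum at 37 °C. RNA was taken at 0 h, 48 h, 96 h and 144 h, and 2 arrays were made per time, 8 in all. The arrays were Affymetrix whole-transcript arrays, on which biotin-labelled fragments bind probes along each transcript. The deposited table held a log2 intensity for 27558 features, and the medians of the 8 arrays lay between 4.52 and 4.63. The number of arrays, 2 per time, limited the precision of every value. No label said whether the 2 arrays of a time came from separate animals, pools or cultures, so the p-values measure only the spread between these arrays, which may be technical. Fold changes below are log2 differences between the means of 2 arrays and 2 arrays, each with its standard error (SE) from the limma model over all 8 arrays. The largest rises and falls are those measured among the named genes. No detection call was used here. A level near the lower quartile of an array, which was 3.23 and 3.25 on the 0 h arrays, is therefore not shown to lie above background. A difference from or to such a level is printed as measured, with no fold, and not every such level is marked below.

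The arrays of a time lay close together and the times lay apart. Across features, the correlation between the 2 arrays of a time was 0.993 at 0 h, 0.993 at 48 h, 0.997 at 96 h and 0.985 at 144 h. Between the means of different times it ran from 0.903, for 0 h and 96 h, to 0.981, for 48 h and 144 h. The first principal component held 60.4% of the variance and placed 0 h first, then 48 h, 144 h and 96 h, so that 144 h and not 96 h lay nearer to 48 h. The second component held 21.8% and set the 96 h arrays, at 48.2 and 46.8, against the 48 h arrays, at -43.7 and -39.2, and the 144 h arrays, at -28.6 and -22.2. By a moderated F test over the 4 times, 13103 features changed, or 47.5% of all. Among 42 ribosomal protein genes, none was called between 48 h and 144 h, while 12 were higher and 7 lower at 96 h than at 48 h. Of all 10707 named genes, 1116 were called between 48 h and 144 h, and 1534 were higher and 1819 lower at 96 h than at 48 h. The ribosomal protein scatter at 96 h goes with every 96 h value given here.

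**Figure D1:**
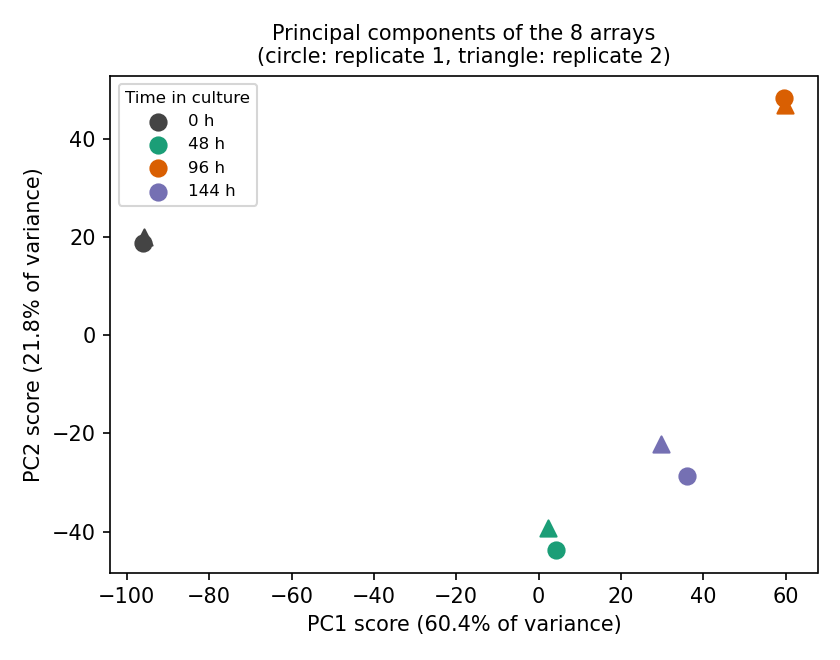
Scores of the 8 arrays on the first 2 principal components of the log2 values, in percent of variance on the axis labels, with 1 point per array, coloured by hours in culture. The 96 h arrays lie at 48.2 and 46.8 on the second component, away from the 48 h and 144 h arrays, which lie between -43.7 and -22.2.

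The comparison of 48 h with 0 h asks what changed in the first part of the culture. Most measured fibrillar matrix, contractile and adhesion genes were called higher, and most cell cycle and interferon response genes lower. Of 17 granulosa identity genes, 8 were lower and 4 higher. No list was called when camera estimated the correlation between genes. HSD3B1, whose enzyme converts pregnenolone to progesterone, rose from a mean log2 level of 3.40 to 10.36, a difference of 6.96 ± 0.16 (SE, n = 2 per time, adjusted p = 3.52e-07). Its 0 h level lay near the lower quartile. HSD17B1, whose enzyme makes estradiol from estrone in granulosa cells, fell from 10.84 to 5.68, a difference of -5.16 ± 0.14 (adjusted p = 4.42e-07). In all, 8260 of 27558 features were called at an adjusted p below 0.05, 4178 higher and 4082 lower, and of these 1658 and 1380 differed at least 2-fold. With 1 feature per named gene, and p-values still adjusted over all 27558 features, 1941 of 10707 genes were higher and 1695 lower.

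The other genes with the largest rises at 48 h were POSTN (6.57 ± 0.13), which encodes the matrix protein periostin, CLIP4 (6.42 ± 0.18), LOX (6.07 ± 0.10), which encodes the collagen cross-linking enzyme lysyl oxidase, and SFRP2 (5.55 ± 0.21, or 3.94 by its other feature), a secreted Wnt modulator. SERPINB2 (5.37 ± 0.23), FN1 (5.14 ± 0.13), LAMB1 (5.06 ± 0.11), ITGA2 (5.04 ± 0.21, or 3.09 to 5.42 by its other features) and SHAS2 (5.01 ± 0.27), the pig hyaluronan synthase 2 gene, followed. The largest falls after HSD17B1 were those of SNX31 (-4.92 ± 0.11), DAPL1 (-4.84 ± 0.16), the chemokine gene CXCL10 (-4.77 ± 0.22), NEBL (-4.74 ± 0.15) and PLA2G4E (-4.66 ± 0.11). MAL2 (-4.44 ± 0.12), the hedgehog ligand gene IHH (-4.33 ± 0.18), DGKB (-4.31 ± 0.13) and RHBG (-4.27 ± 0.16) fell by similar amounts. CLIP4 rose from a mean level of 2.91, and CXCL10 and DGKB fell to 3.01 and 2.67, below the lower quartile. The estrogen receptor gene ESR1 fell too, with a difference of -3.02 ± 0.20, or -2.40 to -2.76 by its other features.

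Among the gene lists, matrix, contractile and adhesion genes rose together at 48 h. Of 19 measured fibrillar matrix genes, 17 were higher and 1 lower, with a median of 2.59 (camera adjusted p = 2.78e-12; adjusted p = 0.124 with an estimated correlation). COL1A1 rose by 2.86 ± 0.19 and COL3A1 by 2.03 ± 0.15, although its features disagreed, with another COL1A1 feature at 0.24 and one whose annotation repeats the symbol at 3.30. Of 11 contractile genes, 10 were higher (median 2.38, camera adjusted p = 2.03e-08; adjusted p = 0.0733 with an estimated correlation), among them TAGLN (4.68 ± 0.11), TPM2 (3.51 ± 0.13), smooth muscle actin ACTA2 (2.85 ± 0.12) and CNN1 (2.59 ± 0.19). Of 16 focal adhesion genes and YAP targets, 12 were higher and none lower (camera adjusted p = 2.87e-07; adjusted p = 0.110 with an estimated correlation), with ITGB3 at 4.90 ± 0.12 and ITGA5 at 2.38 ± 0.20. Of 18 proteases and inhibitors, 11 were higher and 2 lower, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.000454; adjusted p = 0.136 with an estimated correlation). The inhibitor gene TIMP1 rose by 2.03 ± 0.12 and SERPINE2 fell by 2.73 ± 0.14. Where no other count is given here and below, the counts were the same when adjusted over the list alone. No list was called at any time with an estimated correlation.

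Granulosa cell genes, cell cycle genes and interferon genes fell at 48 h. Of 17 granulosa identity genes, 8 were lower, or 9 adjusted over the list alone, and 4 higher (camera adjusted p = 0.0330; adjusted p = 0.176 with an estimated correlation), and this call was lost without 0 h replicate 1 (adjusted p = 0.0522). AMH, the anti-Müllerian hormone gene, differed by -2.36 ± 0.16, NR5A2 by -1.80 ± 0.27, FST by -1.45 ± 0.23 and INHBA, which encodes the activin beta A subunit, by -1.25 ± 0.15. LHCGR, the luteinizing hormone receptor gene, differed by -0.15 ± 0.28 (adjusted p = 0.738). Of 12 mitosis genes, 11 were lower (median -1.72, camera adjusted p = 2.06e-07; adjusted p = 0.110 with an estimated correlation), among them TOP2A (-2.73 ± 0.18), CDC20 (-2.55 ± 0.13), UBE2C (-2.00 ± 0.13) and CENPF (-1.92 ± 0.20). ANLN, named after its value was seen, was the mitosis gene that did not pass, at 0.21. Of 10 DNA replication genes, 9 were lower (camera adjusted p = 5.03e-05; adjusted p = 0.0956 with an estimated correlation), including the cyclin gene CCNE2 (-3.58 ± 0.20) and CDC45 (-1.66 ± 0.11). Of 13 interferon response genes, 12 were lower (median -1.64, camera adjusted p = 2.06e-07; adjusted p = 0.0733 with an estimated correlation), with IFIT1 at -3.31 ± 0.15, IFIT3 at -2.94 ± 0.26 and MX2 at -2.20 ± 0.28.

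Stress and metabolic lists moved in several directions at 48 h. Of 9 p53 targets and senescence genes, 8 were higher (camera adjusted p = 0.000972; adjusted p = 0.124 with an estimated correlation), with the cell cycle inhibitor gene CDKN1A at 2.80 ± 0.15 and PLK2 at 4.24 ± 0.15, while BTG2 fell by 1.65 ± 0.27. Of 13 glycolysis and hypoxia genes, 10 were higher (camera adjusted p = 2.32e-05; adjusted p = 0.110 with an estimated correlation), among them the hexokinase genes HK2 (1.84 ± 0.12) and HK1 (1.62 ± 0.13). Of 18 inflammatory cytokine genes, 12 were higher and 3 lower (camera adjusted p = 0.000396; adjusted p = 0.158 with an estimated correlation): CCL2 rose by 3.62 ± 0.12, LIF by 3.06 ± 0.22 and VCAM1 by 2.64 ± 0.16, and CXCL10 fell. Of 11 heat shock genes, 6 were lower, or 8 adjusted over the list alone (camera adjusted p = 0.00494; adjusted p = 0.136 with an estimated correlation), with DNAJB1 at -2.68 ± 0.11. Of 17 genes of the unfolded protein and amino acid response, 6 were higher and 2 lower, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0380; adjusted p = 0.158 with an estimated correlation), and the risers PSAT1 (2.90 ± 0.22), PHGDH (1.68 ± 0.21) and ASNS (1.38 ± 0.16) make amino acids. Of 11 oxidative phosphorylation genes, 2 were higher, or 4 adjusted over the list alone (camera adjusted p = 0.0330; adjusted p = 0.429 with an estimated correlation). The calls of the unfolded protein and oxidative phosphorylation lists were lost after cyclic loess, with adjusted p = 0.257 and 0.381, and with dim features left out, with 0.122 and 0.107. Without 0 h replicate 1 they were lost too, with 0.0520 and 0.0526, and without 48 h replicate 1 the oxidative phosphorylation call was lost, with 0.0805.

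The other lists did not pass at 48 h, although single members moved far. Of 14 steroidogenesis genes, 6 were higher and 7 lower (camera adjusted p = 0.658), with FDXR at -2.39 ± 0.12. Of 12 ovulation genes, 2 were higher and 5 lower, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.366), with the prostaglandin E synthase gene PTGES at -2.46 ± 0.14. These counts leave out SHAS2, the pig HAS2 gene, which the list holds under its other symbol, and RUNX2 and CEBPB, whose annotation repeats their symbols. With these 3 risers, 5 of 15 were higher and 5 lower, or 6 and 5 adjusted over the list alone, and the test pointed up in place of down (camera adjusted p = 0.658). Of 17 TGF-beta, activin and BMP genes, 9 were higher and 4 lower, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.0913), with SMAD7 at 2.99 ± 0.13 and TGFBR3 at -3.92 ± 0.11. Of 14 insulin-like growth factor genes, 6 were higher and 5 lower, or 6 and 6 adjusted over the list alone (camera adjusted p = 0.902), and the test pointed up while the median was -0.08. Of 9 genes of epithelial to mesenchymal transition, 4 were higher, or 6 with 2 lower adjusted over the list alone (camera adjusted p = 0.0633). This list passed without 0 h replicate 2 (0.0412), 48 h replicate 1 (0.0472) or either 144 h array (0.0351). The TGF-beta list passed without either 144 h array (0.0421), and with TGFB2 and SKIL, whose annotation repeats their symbols (0.0303; adjusted p = 0.160 with an estimated correlation). Of 8 basement membrane genes, 2 were higher and 3 lower (camera adjusted p = 0.960), and the test pointed down while the mean was 0.11. Of 11 immediate early genes, 2 were higher and 6 lower (camera adjusted p = 0.0665), with ATF3 at -3.41 ± 0.19. This list passed after median centring (0.0388) and after cyclic loess (0.0427). Antioxidant genes (5 of 14 higher and 5 lower), cholesterol synthesis genes (2 of 10 higher and 1 lower) and fatty acid genes (6 of 17 higher and 1 lower) had camera adjusted p of 0.660, 0.658 and 0.236.

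The comparison of 144 h with 0 h spans the longest time measured. Most measured matrix and adhesion genes stayed high. Of 17 granulosa identity genes, 10 were lower at 144 h than at 48 h and none higher, and camera did not call this list with an estimated correlation (adjusted p = 0.170). The luteinizing hormone receptor gene was now among the largest falls. GSTA1, which encodes a glutathione transferase also linked to steroid synthesis, differed by -8.39 ± 0.26 (adjusted p = 3.85e-07), or -7.48 by its other feature, to a level of 3.30, near the lower quartile. The next were DAPL1 by -7.95 ± 0.16, HSD17B1 by -6.63 ± 0.14, PLA2G4E by -5.44 ± 0.11 and SNX31 by -5.16 ± 0.11. CXCL10 (-5.01 ± 0.22), LHCGR (-4.95 ± 0.28), NEBL (-4.85 ± 0.15), RGS2 (-4.82 ± 0.17) and the uncharacterised LOC100526118 (-4.74 ± 0.16) completed the largest falls. DAPL1, CXCL10 and LOC100526118 ended at mean levels of 2.90, 2.76 and 2.31, below the lower quartile. The largest rises were those of SFRP2 (7.02 ± 0.21, adjusted p = 3.25e-07, but only 5.26 by its other feature), the endothelial lipase gene LIPG (6.73 ± 0.23), POSTN (6.47 ± 0.13), HSD3B1 (6.46 ± 0.16) and the collagen-binding proteoglycan gene FMOD (6.41 ± 0.26). LOX (6.24 ± 0.10), FN1 (6.10 ± 0.13), DCN (5.99 ± 0.12), COL1A1 (5.96 ± 0.19) and SHAS2 (5.96 ± 0.27) followed, and other features of COL1A1 differed by 2.97 and 6.0. In all, 8845 features were called, 4240 higher and 4605 lower, and 1915 and 1761 of these differed at least 2-fold.

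**Figure D2:**
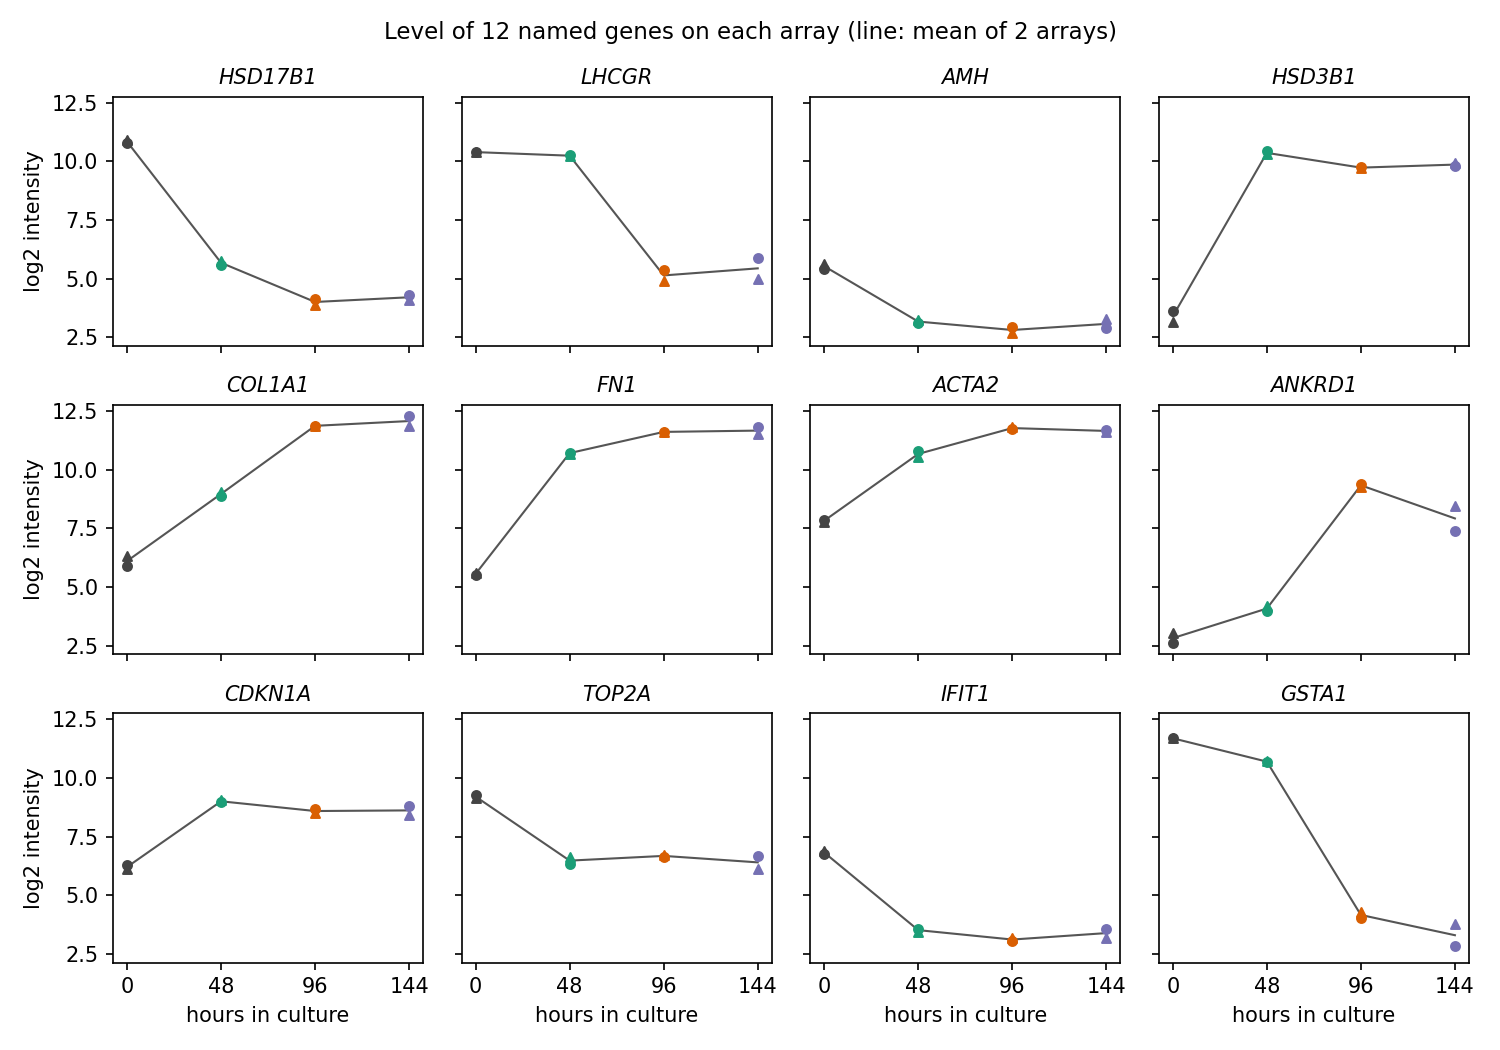
Log2 intensity of 12 genes against hours in culture, with 1 point per array (circle for replicate 1, triangle for replicate 2) and a line through the mean of the 2 arrays of each time. HSD17B1 had fallen by 48 h to 5.68, whereas LHCGR was at 10.24 at 48 h and at 5.14 at 96 h.

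The gene lists at 144 h kept the directions of matrix, contractile and adhesion genes. Of the 19 fibrillar matrix genes, 16 were higher and 1 lower (median 3.29, camera adjusted p = 2.54e-12; adjusted p = 0.139 with an estimated correlation), with COL3A1 at 4.62 ± 0.15. Of the 11 contractile genes, 9 were higher and 1 lower (camera adjusted p = 4.01e-08; adjusted p = 0.0861 with an estimated correlation), with TAGLN at 5.67 ± 0.11, CNN1 at 5.17 ± 0.19, TPM2 at 4.44 ± 0.13 and ACTA2 at 3.82 ± 0.12. Of the 16 focal adhesion genes and YAP targets, 13 were higher (camera adjusted p = 5.37e-09; adjusted p = 0.0998 with an estimated correlation), with ITGB3 at 5.85 ± 0.12, the YAP target ANKRD1 at 5.10 ± 0.31, ITGA2 at 5.01 ± 0.21 (2.79 to 5.26 by its other features) and ITGA5 at 4.54 ± 0.20. Of the 18 proteases and inhibitors, 11 were higher and 3 lower, or 12 and 4 adjusted over the list alone (camera adjusted p = 0.0057; adjusted p = 0.231 with an estimated correlation), with SERPINB2 at 5.49 ± 0.23, PLAU at 2.60 ± 0.13, CTSK at 2.58 ± 0.12, TIMP1 at 1.97 ± 0.12 and SERPINE2 at -2.92 ± 0.14. Of 8 basement membrane genes, 5 were higher and 3 lower and the list did not pass (camera adjusted p = 0.190), with LAMB1 (5.31 ± 0.11), COL15A1 (4.65 ± 0.15) and LAMA4 (4.03 ± 0.18) up and LAMA2 (-3.78 ± 0.16) down. Of 9 genes of epithelial to mesenchymal transition, 5 were higher and 1 lower, among them CDH11 (4.54 ± 0.39) and PRRX1 (3.90 ± 0.38), and the list did not pass (camera adjusted p = 0.0846). It passed without 144 h replicate 1 (0.0455).

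Granulosa identity, cell cycle and interferon genes were low at 144 h. Of the 17 granulosa identity genes, 11 were lower and 2 higher, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.000196; adjusted p = 0.0998 with an estimated correlation), with FST at -4.32 ± 0.23, NR5A2 at -3.94 ± 0.27, AMH at -2.46 ± 0.16 and INHBA at -2.29 ± 0.15. Of the 12 mitosis genes, 11 were lower and 1, ANLN, higher at 0.88 (camera adjusted p = 3.61e-06; adjusted p = 0.139 with an estimated correlation). Of the 10 DNA replication genes, 9 were lower and 1 higher (camera adjusted p = 0.000532; adjusted p = 0.0998 with an estimated correlation), and the riser, named after its value was seen, was CCNE1 at 1.18, a cyclin gene of entry into S phase. The 4 DNA replication genes that moved most were CCNE2 (-4.15 ± 0.20), UHRF1 (-1.75 ± 0.14), CDC45 (-1.74 ± 0.11) and CDC6 (-1.31 ± 0.18). Of the 13 interferon response genes, 12 were lower (camera adjusted p = 1.26e-07; adjusted p = 0.0861 with an estimated correlation), with IFIT1 at -3.43 ± 0.15, MX2 at -2.67 ± 0.28, IFIT3 at -2.40 ± 0.26 and CMPK2 at -2.02 ± 0.18. Of 14 steroidogenesis genes, 4 were higher and 7 lower and the list did not pass (camera adjusted p = 0.190): HSD3B1 rose, and HSD17B1, NR5A2 and FDXR (-3.40 ± 0.12), which encodes the reductase that feeds electrons to mitochondrial steroid enzymes, fell. Of 12 ovulation and cumulus expansion genes, 1 was higher and 5 lower, or 2 and 5 adjusted over the list alone, with ADAMTS1 at 1.91 ± 0.13 and RGS2, PTGES (-3.59 ± 0.14, or -2.89 by its other feature) and BTC (-1.83 ± 0.31) among those that moved (camera adjusted p = 0.0975). With SHAS2, RUNX2 and CEBPB counted, 4 of 15 were higher and 5 lower, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.877).

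Stress, metabolic and cytokine lists also passed at 144 h. Of the 9 p53 targets and senescence genes, 6 were higher and 1 lower, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00431; adjusted p = 0.163 with an estimated correlation), with PLK2 at 3.59 ± 0.15, CDKN1A at 2.41 ± 0.15, CDKN2B at 2.31 ± 0.26 and BTG2 at -2.08 ± 0.27. Of the 18 inflammatory cytokine genes, 9 were higher and 3 lower, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.00321; adjusted p = 0.231 with an estimated correlation), with VCAM1 at 4.69 ± 0.16, CCL2 at 4.61 ± 0.12 and LIF at 3.43 ± 0.22. Of 10 cholesterol synthesis genes, 7 were higher, or 9 adjusted over the list alone (camera adjusted p = 0.00229; adjusted p = 0.369 with an estimated correlation), with SQLE at 1.99 ± 0.28 and SC5D at 1.39 ± 0.23. Of the 13 glycolysis and hypoxia genes, 8 were higher, or 9 with 1 lower adjusted over the list alone (camera adjusted p = 0.00316; adjusted p = 0.163 with an estimated correlation). Of the 11 heat shock genes, 7 were lower, or 7 with 1 higher adjusted over the list alone (camera adjusted p = 0.00401; adjusted p = 0.151 with an estimated correlation). A further 7 lists did not pass at 144 h. TGF-beta, activin and BMP genes (8 of 17 higher and 5 lower), insulin-like growth factor genes (7 of 14 higher and 4 lower) and immediate early genes (3 of 11 higher and 6 lower) had camera adjusted p of 0.494, 0.313 and 0.154. Immediate early genes passed without 144 h replicate 2 (0.0213). Of 17 fatty acid genes, 5 were higher and 3 lower, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.569), and the test pointed up while the median was -0.06. Of 14 antioxidant genes, 4 were higher and 5 lower, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.654). Of 17 unfolded protein genes, 6 were higher and 2 lower, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.304). Of 11 oxidative phosphorylation genes, 2 were higher, or 1 adjusted over the list alone (camera adjusted p = 0.228). Single members of these lists still moved far: IGFBP5 rose by 4.97 ± 0.14, GREM1 by 3.65 ± 0.51, SMAD7 by 3.57 ± 0.13, ACSL4 by 2.43 ± 0.16 and SRXN1 by 2.23 ± 0.11. TGFBR3 fell by 4.44 ± 0.11, GCLC by 2.84 ± 0.11, ATF3 by 2.35 ± 0.19, PAPPA by 2.32 ± 0.12 and NQO1 by 2.13 ± 0.15.

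**Figure D3:**
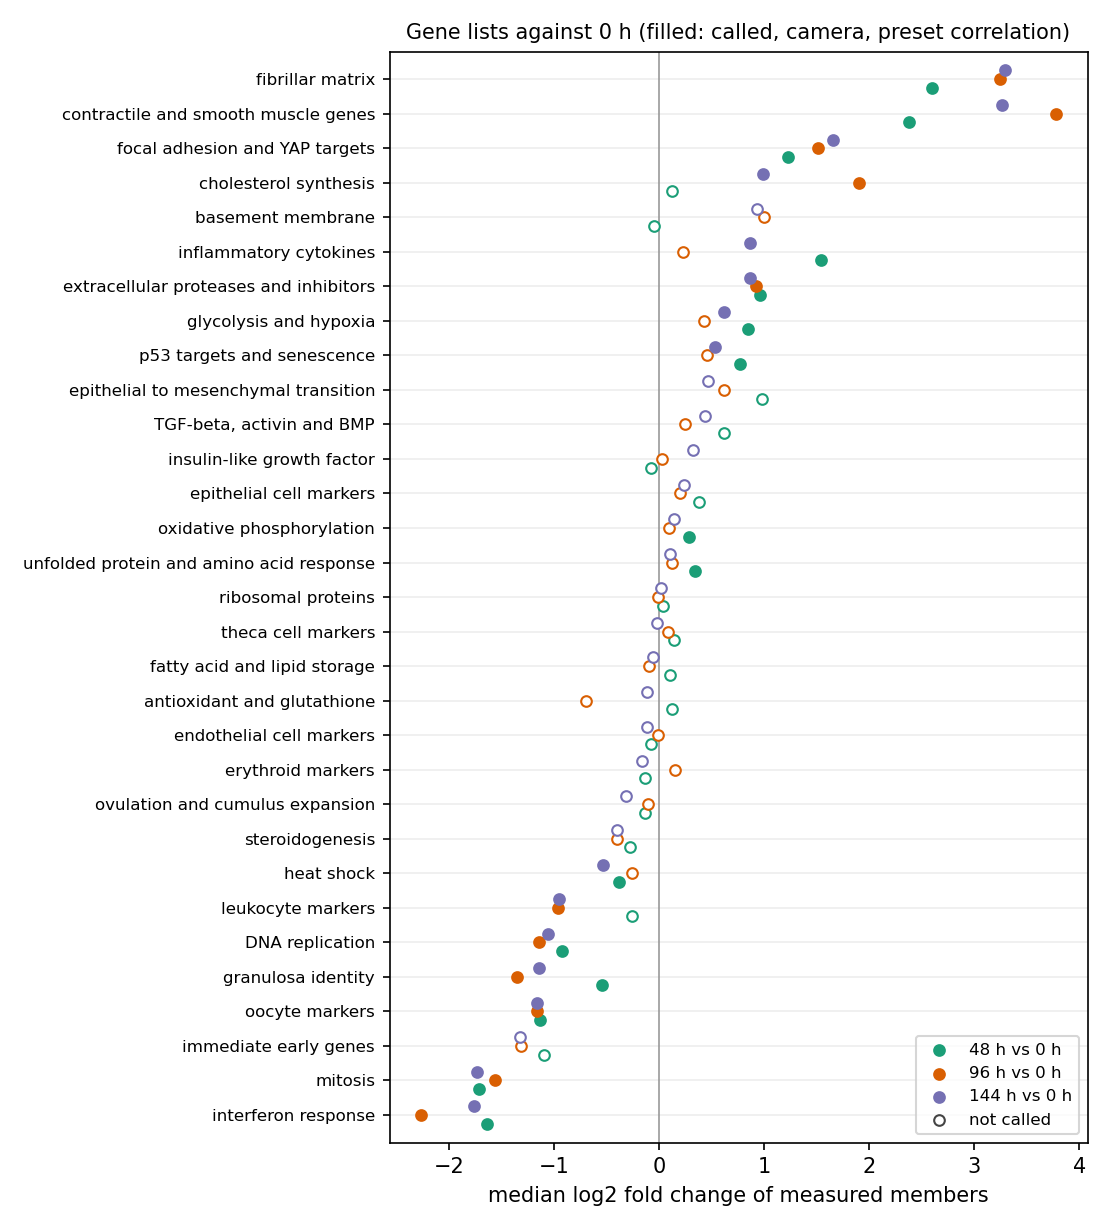
Median log2 fold change of the measured members of each of 31 gene lists against 0 h, with 1 point per list and time, filled where camera with a preset correlation called the list. Fibrillar matrix genes had medians of 2.59, 3.24 and 3.29 at 48 h, 96 h and 144 h, and interferon response genes of -1.64, -2.27 and -1.76.

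The comparison of 96 h with 0 h gave the most calls. Most measured fibrillar matrix, contractile, adhesion and cholesterol synthesis genes were called higher, and most granulosa identity, cell cycle and interferon genes lower. None of these lists was called when camera estimated the correlation between genes. LIPG rose by 7.57 ± 0.23 (adjusted p = 3.09e-07) from a level of 3.36, near the lower quartile, ANKRD1 by 6.51 ± 0.31, LOX by 6.47 ± 0.10, SFRP2 by 6.41 ± 0.21 (4.94 by its other feature) and HSD3B1 by 6.33 ± 0.16. SHAS2 (6.12 ± 0.27), FN1 (6.05 ± 0.13), LAMB1 (5.92 ± 0.11), COL1A1 (5.76 ± 0.19, or 3.42 and 5.90 by other features) and TAGLN (5.75 ± 0.11) followed. The largest falls were those of DAPL1 (-8.05 ± 0.16, adjusted p = 9.14e-08), GSTA1 (-7.53 ± 0.26), HSD17B1 (-6.83 ± 0.14), the uncharacterised LOC100154181 (-6.72 ± 0.17) and PLA2G4E (-5.70 ± 0.11). SNX31 (-5.43 ± 0.11), FST (-5.43 ± 0.23), ESR1 (-5.38 ± 0.20, or -3.24 to -4.23 by its other 3 features), LHCGR (-5.25 ± 0.28) and CXCL10 (-5.17 ± 0.22) came next. ANKRD1 rose from a mean level of 2.82, and DAPL1 and CXCL10 fell to 2.80 and 2.60, below the lower quartile. In all, 11375 features were called, 5228 higher and 6147 lower, and 2469 and 2678 of these differed at least 2-fold. Of the 42 ribosomal protein genes, 20 were called at 96 h against 5 at 48 h and 5 at 144 h. Of all named genes, 44.9% were called at 96 h, 34.0% at 48 h and 36.8% at 144 h. The ribosomal count at 96 h is thus near the overall share, and the counts at 48 h and 144 h lie below it.

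Of the 31 lists, 11 passed at 96 h beside that ribosomal protein scatter. Fibrillar matrix (16 of 19 higher, median 3.24), contractile (10 of 11 higher, median 3.77), and focal adhesion genes (13 of 16 higher, median 1.51) rose, with camera adjusted p = 2.02e-11, 2.41e-08 and 4.54e-08 and with adjusted p = 0.178, 0.0787 and 0.120 with an estimated correlation. Of the 10 cholesterol synthesis genes, 8 were higher, or 9 adjusted over the list alone (median 1.90, camera adjusted p = 0.000294; adjusted p = 0.379 with an estimated correlation), with HMGCS1 at 2.34 ± 0.27, CYP51 at 2.06 ± 0.26, SQLE at 2.04 ± 0.28 and SC5D at 1.32 ± 0.23. Of the 18 proteases and inhibitors, 12 were higher and 4 lower (camera adjusted p = 0.00541; adjusted p = 0.258 with an estimated correlation). Of the 17 granulosa identity genes, 12 were lower and 2 higher (median -1.36, camera adjusted p = 0.000294; adjusted p = 0.120 with an estimated correlation). Mitosis (11 of 12 lower, 1 higher), DNA replication (8 of 10 lower) and interferon response genes (11 of 13 lower) fell with camera adjusted p = 4.89e-05, 0.00108 and 6.53e-07, and had adjusted p = 0.184, 0.120 and 0.0787 with an estimated correlation. The other 2 lists that passed were oocyte and leukocyte markers, given below. The steroidogenesis list did not pass (4 higher and 6 lower of 14, or 4 and 8 adjusted over the list alone, camera adjusted p = 0.164), nor did the antioxidant list (4 higher and 9 lower of 14, camera adjusted p = 0.120).

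Further lists did not pass at 96 h. Glycolysis genes (7 of 13 higher and 2 lower), p53 targets (5 of 9 higher and 2 lower) and heat shock genes (2 of 11 higher and 4 lower) had camera adjusted p of 0.0717, 0.193 and 0.146, with PLK2 at 2.82 ± 0.15 and DNAJB1 at -3.20 ± 0.11. Heat shock genes passed after cyclic loess (0.0350). Of 18 inflammatory cytokine genes, 8 were higher and 4 lower, or 8 and 6 adjusted over the list alone (camera adjusted p = 0.146), with CCL2 at 4.81 ± 0.12. Of 17 TGF-beta, activin and BMP genes, 7 were higher and 5 lower, or 9 and 6 adjusted over the list alone (camera adjusted p = 0.428), with SMAD7 at 4.84 ± 0.13 and TGFBR3 at -4.46 ± 0.11. Of 17 fatty acid genes, 8 were higher and 6 lower, or 8 and 7 adjusted over the list alone (camera adjusted p = 0.476), and the test pointed up while the median was -0.10. Ovulation genes (2 of 12 higher and 5 lower), basement membrane genes (5 of 8 higher and 3 lower) and genes of epithelial to mesenchymal transition (5 of 9 higher and 1 lower) had camera adjusted p of 0.353, 0.231 and 0.0581, with RGS2 at -4.89 ± 0.17, LAMA2 at -3.99 ± 0.16 and CDH11 at 4.14 ± 0.39. With SHAS2, RUNX2 and CEBPB counted, 5 of 15 ovulation genes were higher and 5 lower, and the test pointed up in place of down (camera adjusted p = 0.787). The transition list passed without 0 h replicate 2 (0.0317), 96 h replicate 2 (0.0485) or either 144 h array (0.0401). Immediate early genes (5 of 11 higher and 6 lower), unfolded protein genes (7 of 17 higher and 4 lower), insulin-like growth factor genes (4 of 14 higher and 5 lower) and oxidative phosphorylation genes (4 of 11 higher and 4 lower) had camera adjusted p of 0.428, 0.476, 0.966 and 0.716.

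Between the later times, 96 h differed most from its neighbours. From 48 h to 96 h, 3683 features were higher and 4406 lower, or 8089 in all. The largest rises were those of ANKRD1 (5.25 ± 0.31), TMEM255A (4.94 ± 0.51), LIPG (4.62 ± 0.23), the integrin gene ITGA8 (4.36 ± 0.26) and LTBP2 (4.29 ± 0.17). The largest falls were those of GSTA1 (-6.53 ± 0.26), LHCGR (-5.10 ± 0.28), LIPH (-4.35 ± 0.35), LOC100526118 (-4.04 ± 0.16) and DDX60 (-3.98 ± 0.21, or -2.54 by its other feature). Without 48 h replicate 1 the count was 5214, and without 96 h replicate 1 or 2 it was 4198 or 4439.

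From 96 h to 144 h, 3333 features were higher and 2782 lower, or 6115 in all. DDX60 (3.38 ± 0.21, or 1.97 by its other feature), DPM3 (3.35 ± 0.14), LOC100154181 (3.28 ± 0.17), TXNIP (2.91 ± 0.22) and TMEM141 (2.65 ± 0.15) rose most. The 5 largest falls were those of 3 uncharacterised non-coding genes, LOC100525935 (-3.29 ± 0.24), LOC100627892 (-3.07 ± 0.23) and LOC100525590 (-2.98 ± 0.14), of ITGA4 (-2.79 ± 0.32) and of the ribosomal protein gene RPS16 (-2.79 ± 0.15). Of all features, 2022 were higher and 2515 lower at 96 h than at both 48 h and 144 h, each by its own test, and 4087 of these were not called between 48 h and 144 h. Without 96 h replicate 1 or 2 the count from 96 h to 144 h was 2437 or 2594.

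**Figure D4:**
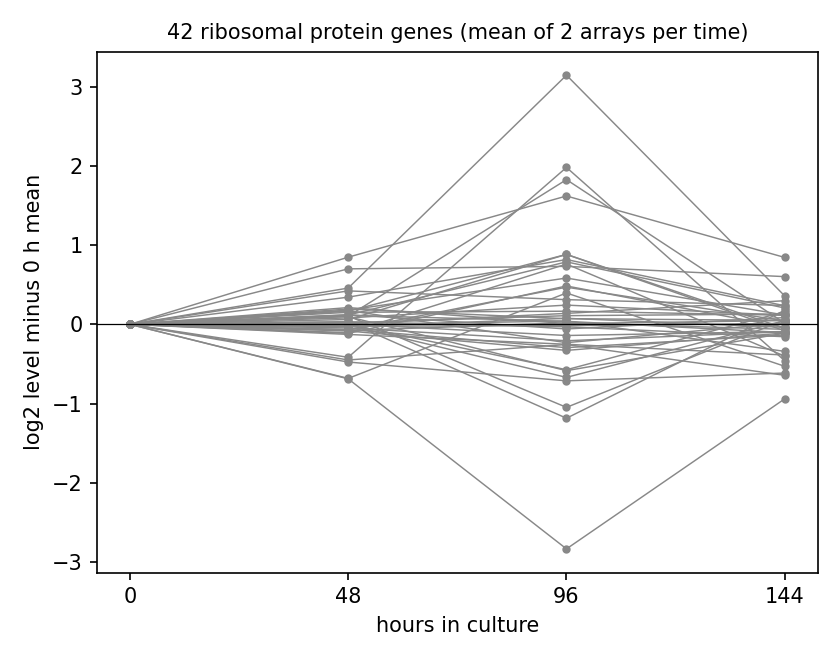
Mean log2 level of each of 42 ribosomal protein genes minus its own mean at 0 h, against hours in culture, with 1 line per gene and 2 arrays per mean. From 48 h to 96 h, 12 genes were called higher and 7 lower, and from 48 h to 144 h none was called. Of all 10707 named genes, 1534 were called higher and 1819 lower from 48 h to 96 h.

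From 48 h to 144 h, which leaves the 96 h arrays out of the difference, 1190 features were higher and 1191 lower, or 2381 in all. ITGA8 (5.10 ± 0.26), the aminopeptidase gene ANPEP (4.65 ± 0.19), COL15A1 (4.31 ± 0.15), LOC100513296 (3.91 ± 0.31) and ANKRD1 (3.84 ± 0.31) rose most. UNC45B, whose annotation repeats its symbol and which was named after its value was seen, rose by 4.32. GSTA1 (-7.39 ± 0.26, or -6.47 by its other feature), LHCGR (-4.80 ± 0.28), LOC100526118 (-4.14 ± 0.16), LIPH (-3.57 ± 0.35) and the protease inhibitor gene SPINK5 (-3.54 ± 0.34) fell most. Granulosa identity genes fell further, with 10 of 17 lower and none higher (camera adjusted p = 8.35e-07; adjusted p = 0.170 with an estimated correlation), and 8 of 11 contractile genes rose and 1 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 1.81e-05; adjusted p = 0.170 with an estimated correlation). Focal adhesion genes (7 of 16 higher, or 9 adjusted over the list alone) and cholesterol synthesis genes (4 of 10 higher, or 8 adjusted over the list alone) also rose, with camera adjusted p = 5.74e-05 and 2.56e-05, and with adjusted p = 0.298 and 0.377 with an estimated correlation. Leukocyte markers fell in the same comparison, with 4 of 17 lower and none higher, or 9 lower adjusted over the list alone (camera adjusted p = 0.000693; adjusted p = 0.377 with an estimated correlation). Steroidogenesis genes fell, with 6 of 14 lower and 2 higher, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0125; adjusted p = 0.298 with an estimated correlation). Fibrillar matrix genes rose, with 8 of 19 higher and 1 lower, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.000693; adjusted p = 0.413 with an estimated correlation). Basement membrane genes passed upward with 3 of 8 higher and 1 lower (camera adjusted p = 0.0448; adjusted p = 0.377 with an estimated correlation). Antioxidant genes passed downward with 3 of 14 lower (camera adjusted p = 0.00748; adjusted p = 0.298 with an estimated correlation). Ovulation genes passed downward with 3 of 12 lower, or 4 with 1 higher adjusted over the list alone (camera adjusted p = 0.0448; adjusted p = 0.298 with an estimated correlation). The ovulation call was lost with SHAS2, RUNX2 and CEBPB counted (0.1), and the TGF-beta list passed with TGFB2 and SKIL counted (0.0418). The count of 2381 rested on few arrays. It was 825 with only these 4 arrays, 1576 without the 96 h arrays (chosen after seeing the data) or without either of them, 1070 and 1231 without 48 h replicate 1 and 2, and 3879 without 144 h replicate 1. Where 1 array of a time is left, it is assumed to vary like the other groups. Without the 96 h arrays, 48 h against 0 h gave 6830 features and 144 h against 0 h gave 7454.

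Calls against 0 h were shared between times. At all 3 times, 2447 features were higher and 2788 lower, 5235 in all, where independent lists would share 121.9 and 152.1. In 20 simulations of unchanged groups that shared simulated 0 h arrays, the mean was 0. Unchanged groups give almost no calls, so this 0 does not measure how far shared arrays raise the overlap of called features. The covariance of the fold changes was 0.515 for 48 h and 96 h, 0.529 for 48 h and 144 h and 0.668 for 96 h and 144 h, against 0.0145, 0.0146 and 0.0146 in the simulations. The correlations across features, which are not independent replicates, were 0.739, 0.864 and 0.832, against 0.498, 0.5 and 0.501. The simulated covariance holds what the shared arrays add, whereas the overlap of independent lists does not. The 0 h arrays are too few to give each comparison 2 of its own, so part of the excess of the overlap over independent lists may come from the shared arrays. Between 48 h and 96 h 337 features were called in opposite directions, and between 48 h and 144 h 70 were. With a fold of at least 2 asked for as well, 2044 features were shared.

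Markers of other cell types that the samples could hold were measured beside these groups. Oocyte markers fell: of 11, 9 were lower at 48 h (median -1.13, camera adjusted p = 6.78e-06; adjusted p = 0.0733 with an estimated correlation), 7 at 96 h, or 8 adjusted over the list alone (camera adjusted p = 0.00108; adjusted p = 0.120 with an estimated correlation), and 8 at 144 h, or 9 adjusted over the list alone (camera adjusted p = 6.68e-05; adjusted p = 0.0998 with an estimated correlation). The zona pellucida genes ZP4 and ZP2 differed by -2.90 ± 0.19 and -2.04 ± 0.15 at 48 h, the oocyte growth factor gene BMP15 by -2.22 ± 0.20 and BTG4 by -2.16 ± 0.17. Of 17 leukocyte markers, 2 were lower and 1 higher at 48 h (camera adjusted p = 0.246), 11 lower and 2 higher at 96 h, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.00541; adjusted p = 0.395 with an estimated correlation), and 11 lower and 2 higher at 144 h (camera adjusted p = 0.00401; adjusted p = 0.368 with an estimated correlation). The complement gene C1QB differed by -2.73 ± 0.42 at 96 h, FCER1G by -2.97 ± 0.40, CD53 by -2.57 ± 0.32 and C1QC by -2.18 ± 0.27. The 96 h call of this list was lost with dim features left out (adjusted p = 0.0699).

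Theca, endothelial, erythroid and epithelial markers did not pass at any time. Of 5 theca markers, 2 were higher and 1 lower at 48 h and 1 each way later (camera adjusted p = 0.658, 0.743 and 0.821). At 144 h the test of the theca list pointed up while its median was -0.02. The theca riser DCN, which is also on the matrix list, reached 5.99 ± 0.12 at 144 h, INSL3 differed by -1.60 ± 0.12, and CYP17A1 by -0.17 ± 0.14 (adjusted p = 0.434). Of 8 endothelial markers, 1 was higher at each time and 1, 1 and 2 lower (camera adjusted p = 0.658, 0.743 and 0.498), with PECAM1 at 1.14 ± 0.15, FLT1 at -0.95 ± 0.14 and KDR at -0.66 ± 0.12 at 144 h, although the other feature of KDR differed by 0.13. Of 5 erythroid markers, 1 was lower at each time and 1, EPB42, higher at 144 h, where 1 was higher and 2 lower adjusted over the list alone (camera adjusted p = 0.660, 0.966 and 0.723). At 96 h the test of this list pointed up while its mean was -0.02. The call of HBB, at a log2 level of 2.90 at 0 h, was lost at 144 h without either 0 h array, without 144 h replicate 1 (-0.34) and with only the 4 arrays compared, and that of EPB42 without 0 h replicate 2. Of 6 epithelial markers, 3, 1 and 2 were higher and none lower, with 1 lower at 48 h and 1 at 144 h adjusted over the list alone (camera adjusted p = 0.0979, 0.159 and 0.167), with DSP at 2.75 ± 0.16 and KRT19 at 2.62 ± 0.52 at 144 h, or 1.66 without 144 h replicate 2. Ribosomal proteins served as a flat group. Of 13 on the list, 1 was higher at 48 h, or none adjusted over the list alone, and none at 144 h, with medians of 0.03 and 0.01. At 96 h 4 were higher and 1 lower, or 4 and 2 adjusted over the list alone, and the test pointed up while the median was -0.02. This list did not pass (camera adjusted p = 0.658, 0.798 and 0.940), and its direction turned at all 3 times after cyclic loess.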

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

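The fit without the 96 h arrays and the wider naming of features were chosen after seeing the data, and every other setting was chosen before the data were examined. No scaling moved the share of higher calls by over 10 points, the largest move being from 46.0% to 53.7% for 96 h against 0 h after median centring. With an estimated correlation in camera 0 lists passed at 48 h, 0 at 96 h and 0 at 144 h, in place of 15, 11 and 15. Lists whose estimated correlation lay below the preset 0.01 lost their calls too. Interferon response genes at 48 h, with an estimated correlation of -0.042, went from a camera adjusted p of 2.06e-07 to 0.0733. The size of the correlation alone therefore does not account for the loss. Camera with an estimated correlation was not run on the simulated arrays, so how often it would call a moved list is unknown. Its lack of calls is no evidence that the lists stayed still. With a fold of at least 2 the overlap was 2044 features, by construction. In a fit that held only 1 feature per named gene, p-values were adjusted over those 10707 features and not over all. The counts were then 3928, 5054 and 4257 for 48 h, 96 h and 144 h against 0 h. They were 3638 for 96 h against 48 h, 2746 for 144 h against 96 h, 1420 for 144 h against 48 h, and 5906 over time. At an adjusted p below 0.01 limma called 5147 features for 48 h against 0 h, 4688 for 96 h against 48 h, 3033 for 144 h against 96 h and 1120 for 144 h against 48 h. For 144 h against 48 h, 825 were called with only the 4 arrays compared and 1576 without the 96 h arrays, and both fits hold fewer arrays.

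Leaving out 1 array at a time, where a lone array is assumed to vary like the other groups, gave 4198 to 10294 features for 96 h against 48 h, 2437 to 7320 for 144 h against 96 h and 1070 to 3879 for 144 h against 48 h. The highest count of each of these comparisons came without a 144 h array. For 96 h against 48 h that array is not in the difference, but it enters the pooled spread. The replicate block gave 8233, 11398 and 8831 features for 48 h, 96 h and 144 h against 0 h and changed no list call. The deviations of same-numbered arrays correlated, across features, between -0.04 and 0.19 over the 6 pairs of times, with the highest value for 48 h and 144 h. These correlations cannot show whether same-numbered arrays share an animal, pool or culture, and no label says what the numbers pair.

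Every direction against 0 h that turned belonged to a list or gene that was not called. With the wider naming these were ovulation genes at 48 h (adjusted p = 0.658) and 96 h (0.787), through the 3 risers it adds. For the others the cause was not tested. After cyclic loess these were endothelial (adjusted p = 0.951), antioxidant (0.734) and insulin-like growth factor (0.889) genes at 48 h, insulin-like growth factor genes at 96 h (0.942), and ribosomal proteins at 48 h, 96 h and 144 h (0.298, 0.759 and 0.227). With dim features left out they were endothelial genes at 48 h (0.951), insulin-like growth factor genes at 96 h (0.985) and ribosomal proteins at 144 h (0.886), and with median centring insulin-like growth factor genes at 96 h (0.928). Over the arrays left out, the adjusted p of lists that turned ran from 0.809 to 0.952 for basement membrane at 48 h, 0.795 to 0.970 for erythroid, 0.910 to 0.984 for insulin-like growth factor and 0.572 to 0.986 for ribosomal genes at 96 h, and 0.559 to 0.840 for theca and 0.717 to 0.930 for ribosomal genes at 144 h. The 144 h change of GLI1 ran from -0.073 to 0.34 and that of CLDN5 from -0.48 to 0.036. From 48 h to 144 h the wider naming gained the TGF-beta call (0.0418) and lost the ovulation call (0.1, from 0.0448). Among list calls against 0 h, the wider naming gained 1 (TGF-beta genes at 48 h, 0.0303), cyclic loess gained 2 and lost 2, median centring gained 1, leaving out dim features lost 3, and leaving out 1 array at a time gained 12 and lost 4. The lists gained were immediate early, heat shock, epithelial to mesenchymal transition and TGF-beta genes. The number of arrays limits these comparisons.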

Other observations

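The tests of exchanged labels and of ribosomal protein scatter were chosen after the result was seen, and the other tests before.

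The 96 h arrays stood apart from those before and after them. Over 42 ribosomal protein genes the SD of the 96 h level around the mean of 48 h and 144 h was 6.12 times the SD of 144 h minus 48 h, against 1.1 over all named genes, and over 54 proteasome and mitochondrial ribosome genes it was 3.11 times. For the difference between 2 features of 1 gene, over 473 genes with 2 features above the median level, the ratio was 2.54. Without a probe-level offset it was predicted to be at most 1.1. An array-wide or probe-level technical offset at 96 h may therefore account for part of the changes at 96 h. An exchange of the 96 h and 144 h labels stays open too, since the 144 h mean lay between the 48 h and 96 h means in 48.3% of 5550 named genes called over time and the 96 h mean between the others in 20.4%. No label gives a batch, so a batch of the 96 h arrays and a biological change at 96 h cannot be told apart.

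Many measured oocyte transcripts were higher at 0 h than later. Of a second list of 14 measured oocyte genes, 57.1% were called lower at 48 h, against 15.8% of all named genes. Among those called lower, FBXO43 and NLRP9 were at log2 levels of 3.20 and 3.48 at 0 h, near the lower quartile, and are not shown to lie above background. Log2 levels at 0 h were 9.96 for KIT, which other ovarian cells also express, 6.18 for H1FOO, 6.07 for KPNA7, and 6.16 for ZP4 and 5.48 for BMP15 on the first list, and levels of different probes do not rank abundance. KIT stayed at 8.97, 9.16 and 8.18 at 48 h, 96 h and 144 h. CPEB1, named after its value was seen, was called lower at 48 h only. It was at 4.41 at 0 h, 3.60 at 48 h, 4.37 at 96 h and 4.34 at 144 h. Oocytes among the 0 h cells that did not persist in culture are a candidate source, but not for the later levels of KIT and CPEB1. A fall of the oocyte transcripts within granulosa cells was not tested.

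Leukocyte transcripts were lower at 96 h than at 0 h, but few were called lower at 48 h. Of a second list of 14 measured leukocyte genes, 57.1% were called lower at 96 h, against 23.4% of all named genes, and 7.14% at 48 h. The median was -0.26 at 48 h and -0.97 at 96 h on the first list, and -0.16 and -0.52 on the second. A smaller fall by 48 h is therefore not excluded by the count of calls. At 144 h 50% were lower, against 17.6%, and 11 of 17 on the first list, so an offset of the 96 h arrays alone does not account for the falls at 144 h. The 2 arrays at 144 h lay apart, at 4.17 and 5.77 for C1QB and at 3.69 and 5.16 for FCER1G, so the size of these falls is uncertain. On the first list C1QB was at a log2 level of 7.34 at 0 h, FCER1G at 6.73 and C1QC at 6.40, while CD14 and LYZ on that list, named after their values were seen, rose by 0.76 and 1.75 at 96 h. Fewer leukocytes in the cultures may account for the falls but not for these rises.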
